A study of Mus musculus with 4 samples.

How the data were processed

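Quiescent mouse NIH3T3 fibroblasts, grown in 10% serum and kept serum-free for 24 h, were fixed with formaldehyde for 10 min. Per the labels, chromatin was sheared to about 800 bp, precipitated with an antibody against p27 or with control IgG, and compared with 200 ng of input DNA after ligation-mediated amplification. The labels give Cy5 for the precipitate and Cy3 for the input, with no dye swap. Both antibodies were hybridised to each of the 2 array designs, which gives 4 arrays and 1 per antibody and design. The number of arrays limits the precision, and slide and antibody cannot be separated.

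The deposited tables of all spots give, for each array, a log2 ratio of precipitate over input that the authors normalized within the array, a mean log2 intensity without background subtraction, and a spot p-value. Per the submitters' processing notes the tools were Agilent Feature Extraction and limma, whose settings are not given in the sources used here. The deposited scanner output of 2 arrays (IgG on design 1 and p27 on design 2) holds, per the file headers of Agilent Feature Extraction 9.5.1.1, a log10 ratio of processed signals, processed and raw intensity values of both channels and the spot p-value of the scanner's error model. Such a p-value describes 1 spot and has no replicate behind it. The spots of the 2 arrays were matched to the deposited tables, and the authors' log2 ratios followed the raw signal ratio after removal of a trend with intensity (r of 0.999 across probes on both arrays; probes are not independent replicates). Of their probes, 99.4% were well above background in both channels. The median signal over background was 14.8 and 13.6 for the precipitate and 12.7 and 10.0 for the input. The authors also deposited a table of probes with a log2 difference above 2 and a gene table with the number of consecutive probes, which were used for the fourth comparison, for the choice of 5 named genes and for the account of the probes left out.

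The difference of a probe is its p27 log2 ratio minus its IgG log2 ratio on the same design. Control spots and probes without a ratio on either array were left out, which kept 236689 probes on design 1 and 235978 on design 2. No further normalization, filter or pseudocount was applied. A gene was called when at least 2 neighbouring probes, with starts at most 1000 bp apart, had a difference above 2; the same rule below -2 is the control of the opposite sign. The 16853 genes had a median of 28 probes. Runs were set beside 100 shuffles of the values over the probes of a design. Distances to a transcription start are the smallest among the transcripts that the array annotation lists for a probe, of RefSeq, MGC or Ensembl, and their sign follows that transcript; distances for named genes are to the gene's own RefSeq start where stated so. Divergent promoters are as annotated on the array. Gene symbols of the annotation were brought up to date with the RefSeq gene table: 13215 matched a current symbol, 3384 a RefSeq accession and 174 a synonym, and 135 were kept as they stood.

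A gene's score is its highest mean difference over 3 neighbouring probes, less the median of its design. For each of 17 lists the median score was placed among 10000 random lists of the same size, drawn with replacement from genes of the same design in the same of 5 classes of probe number and of mean signal. The thresholds, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are the 8 per design with the highest mean difference over a run above 2, up to 3 per design with the lowest over a run below -2, from each list up to 3 called members or otherwise the highest one, up to 5 of the deposited gene table with the most consecutive probes, and Cdkn1b, Ccna2, E2f1, Rbl1, Rbl2, E2f4, Myc, Gapdh and Actb. Genes with near-identical copies were to be named as uncertain. A gene that this rule selects is not reported here.

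Alternatives covered centring, quantile normalization, a loess of the difference on signal, dim probes left out, p27 over input alone, scanner signals, other thresholds, run lengths and gaps, other scores and other matching of the random lists. Confidence intervals of shares are 95% Wilson intervals. The calling and the lists were tested on simulated data with independent normal noise at the robust SD of each design, 0.46 and 0.39. Peaks of 2.5 over 3 probes were called at 88.0% of 50 genes, peaks of 1.5 at 4.0%, and 0 of 16647 genes without a peak were called. Real differences had a larger SD, 0.56 and 0.49. The 0 calls follow largely from the noise chosen and give no false-call rate for these arrays. Of 200 simulated lists without peaks, 8 lay outside the central 95%. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the background model of the scanner signals. No expression data were used here, and no tests or p-values across arrays were computed.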

Results

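Chromatin bound by p27 was mapped in quiescent NIH3T3 cells, a mouse embryonic fibroblast line that stops dividing when serum is withdrawn. The protein p27 (gene Cdkn1b) is an inhibitor of cyclin-dependent kinases that accumulates in resting cells. DNA precipitated with an antibody against p27, or with control IgG, was labelled with Cy5 and hybridised against Cy3-labelled input DNA on promoter arrays that tile the surroundings of mouse transcription starts with several probes per gene. The array set has 2 designs: design 1 covers chromosomes 1 to 8 and part of 9, and design 2 covers the rest of the genome. There was 1 array per antibody and design, 4 arrays in all, so no value below has a replicate check and no test across arrays was possible. Values are log2 ratios of precipitate over input, and the difference is the p27 ratio minus the IgG ratio of the same probe. Positions are those printed by the array annotation; the genome build is not given in the sources used here.

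The first comparison asked which promoters p27 occupies in resting fibroblasts beyond the IgG background. The p27 signal exceeded IgG over short blocks of neighbouring probes at 396 of 16853 genes (2.35%). Genes that share a region are each counted, and there were 353 runs of at least 2 probes above 2. The opposite sign was reached at 4 genes. By mean over a run of any length, the difference on design 1 was highest at Mrpl19, which encodes a protein of the mitochondrial ribosome. It had 4.48 over 2 neighbouring probes (chromosome 6, 81931557 to 81931815). On design 2 this mean was highest at Vta1, which encodes a factor of endosomal sorting, with 4.37 over 2 probes (chromosome 10, 14395780 to 14395994). In both regions the p27 ratio itself was high, at 3.75 for Mrpl19 and 3.63 for Vta1, and the IgG ratio lay below input, at -0.73 and -0.74. The highest single probes lay elsewhere, with a difference of 5.48 at Psmd9 on design 1 and of 5.93 on design 2.

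The other genes at the top of design 1 serve varied basic functions. Pold3, a subunit of DNA polymerase delta, had a mean difference of 4.14 over 3 probes (chromosome 7, 99995447 to 99995799). Wdr5, a core part of histone methyltransferase complexes, had 3.96 over 3 probes on chromosome 2 (27336942 to 27337248); the highest of them lies 6 bp from an annotated start but 356967 bp from the RefSeq start of Wdr5 in the array annotation. Vps72, a subunit of complexes that exchange histone variants, had 4.04 over 3 probes on chromosome 3 (95192329 to 95192633); those probes lie next to the start of the gene transcribed in the other direction and at -3981 bp from the RefSeq start of Vps72. The remaining genes were Uevld (4.15), a relative of ubiquitin-conjugating enzymes, Ttc14 (4.14), Cfap69 (4.13), a protein of cilia and flagella, and Kctd3 (3.99). On design 2, Rtcb, the ligase that joins spliced tRNA, had 3.94 over 2 probes (chromosome 10, 85387439 to 85387700). Aarsd1, which edits mischarged alanyl-tRNA, had 3.85, as did Rhot1, which links mitochondria to microtubule motors. Ccdc92b had 3.88 in a region annotated as downstream of it, at 29758 bp from its RefSeq start and -177 bp from another annotated start. Stxbp4 had 3.72 over 3 probes in a region that it shares with Cox11, an assembly factor of cytochrome c oxidase. The divergent pair 4933427D14Rik and Txndc17, the latter a thioredoxin-like protein, shared a region with 3.72, at -72 bp from the RefSeq start of Txndc17 and -4110 bp from that of 4933427D14Rik.

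**Figure D1:**
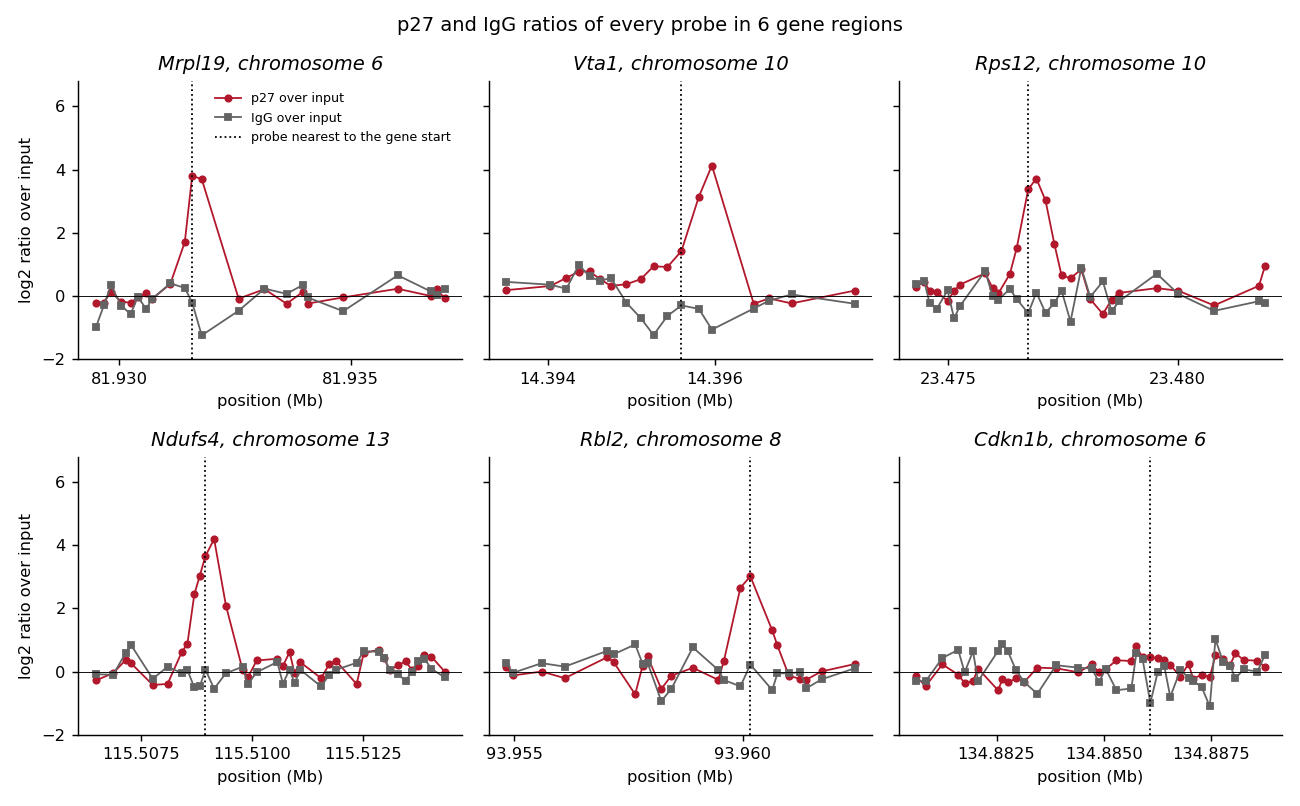
Log2 ratio over input (vertical axis) of every probe against its position in Mb (horizontal axis) in 6 gene regions, red circles for p27 and grey squares for IgG, with a dotted line at the probe nearest to the gene's own RefSeq start. The p27 ratio peaks close to the start at Mrpl19, Vta1, Rps12, Ndufs4 and Rbl2, where the mean differences over each run are 4.48, 4.37, 3.69, 3.38 and 2.96, and stays low at Cdkn1b, whose highest mean over 3 probes is 0.69.

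Genes fixed in advance for their part in quiescence behaved unequally. Rbl2, which encodes the pocket protein p130 of resting cells, was called with a mean difference of 2.96 over 2 probes (chromosome 8, 93959923 to 93960192). Its relative Rbl1, which encodes p107, had 1.74 over its highest 3 probes and was not called. The values of the other genes in this set, over their highest 3 probes, were 1.03 for Myc, 1.02 for E2f4, 0.74 for Ccna2 (cyclin A2), 0.69 for Cdkn1b itself and 0.66 for E2f1. The p27 ratio of the E2f4 probes was -0.39, so that value came from a low IgG ratio of -1.40. The reference genes Actb and Gapdh had 0.84 and 0.52. Each of these values is the highest in its region, so a value above 0 is not by itself a sign of p27. Ranked among all genes after subtraction of the design median, Cdkn1b was at the 53.2th percentile, E2f1 at 49.7 and Ccna2 at 58.4. E2f4 was at 78.9, Myc at 83.7 and Rbl1 at 96.5, with Actb at 66.7 and Gapdh at 35.3.

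The 4 genes on the opposite side were Cdkn1a (-2.39), which encodes the related kinase inhibitor p21, Hnmt (-2.18), which inactivates histamine, Kcna6 (-2.17), a potassium channel, and Lyzl6 (-2.23), a lysozyme-like protein. At Cdkn1a and Hnmt the IgG ratio was 2.22 and 1.53, against p27 ratios of -0.17 and -0.65. At Kcna6 and Lyzl6 the p27 ratio was the larger part, at -1.32 and -1.40, against IgG ratios of 0.85 and 0.83. None of the 4 was called with the p27 ratio alone.

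**Figure D2:**
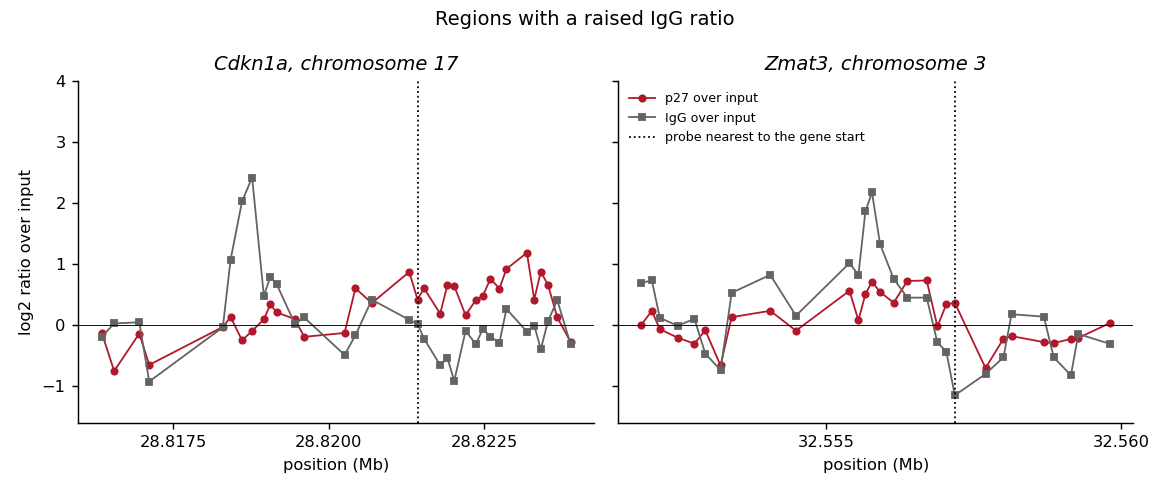
Log2 ratio over input (vertical axis) of every probe of Cdkn1a and Zmat3 against its position in Mb (horizontal axis), red circles for p27 and grey squares for IgG, with a dotted line at the probe nearest to the gene's own RefSeq start. IgG peaks upstream of Cdkn1a and inside Zmat3, with means over 3 probes of 1.84 and 1.79, where the p27 means are -0.07 and 0.59.

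Across all probes, the difference was above 2 at 1100 of 236689 probes on design 1 (0.465%) and at 679 of 235978 on design 2 (0.288%). It was below -2 at 67 and 52. Neighbouring probes above 2 formed 212 runs of at least 2 probes on design 1 and 141 on design 2, the longest with 7 and 5 probes. Shuffling the values over the probes 100 times gave at most 10 and 6 runs. Among probes above 2 the median p27 ratio was 1.82 and 2.04, and the median IgG ratio was -0.72 and -0.50. Of the same probes, 36.8% and 30.2% had an IgG ratio below -1, so a low IgG value is part of many differences. The count of genes on the low side differed between settings. In 1 setting the scanner's processed signals replaced the deposited values of the 2 arrays that have them. It called 451 genes above and 146 below, 138 of the latter on design 1, against 396 and 4. Only 1 array of each pair was replaced, IgG on design 1 and p27 on design 2. The deposited ratios of these arrays had slopes of 0.649 and 0.693 on the scanner ratios. The 2 arrays of a pair were thus on unlike scales in that setting. Raw scanner signals with a background model gave 426 and 13, and quantile normalization gave 259 and 13.

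The second comparison asked where in the tiled regions the p27 signal lies. It was concentrated at transcription starts on both array designs. On design 1, 83.0% of the probes above 2 (95% Wilson interval 80.7 to 85.1) lay within 500 bp of a start, against 19.4% of all probes. On design 2 the share was 88.2% (85.5 to 90.4), again against 19.4%. Bbs5, a part of the cargo complex of cilia, gives an example: its run of 5 probes with a mean of 2.83 has its highest probe 16 bp downstream of the start (chromosome 2, 69447676 to 69448372). The runs of Ndufs4 and Ndufaf5, a subunit and an assembly factor of respiratory complex I, each span 5 probes close to their starts, with means of 3.38 and 3.08.

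Promoters that serve genes in both directions had probes above 2 more often, in raw shares not matched on signal or probe length. Among probes within 500 bp of a start, 5.66% at divergent promoters and 1.80% at the others were above 2 on design 1. On design 2 the shares were 3.86% and 1.18%. The mean IgG ratio was also lower at divergent promoters, -0.18 against -0.10 on design 1 and -0.14 against -0.07 on design 2. Pairs of this kind were Eef1b2 with Ndufs1, Lsm3 with Xpc, Aurka with Cstf1 and Rpl3 with Syngr1, and their mean differences were 3.20, 3.32, 2.23 and 3.66. Among the chromosomes of design 2, the share of probes above 2 near starts was lowest on X, 0.73%, and highest on chromosome 11, 1.75%. Among those of design 1 it was highest on chromosome 5, 2.65%. Probes below -2 were not concentrated there, with 11.9% (6.2 to 21.8) and 11.5% (5.4 to 23.0) within 500 bp. The intervals cover counting error only, and neighbouring probes are not independent.

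**Figure D3:**
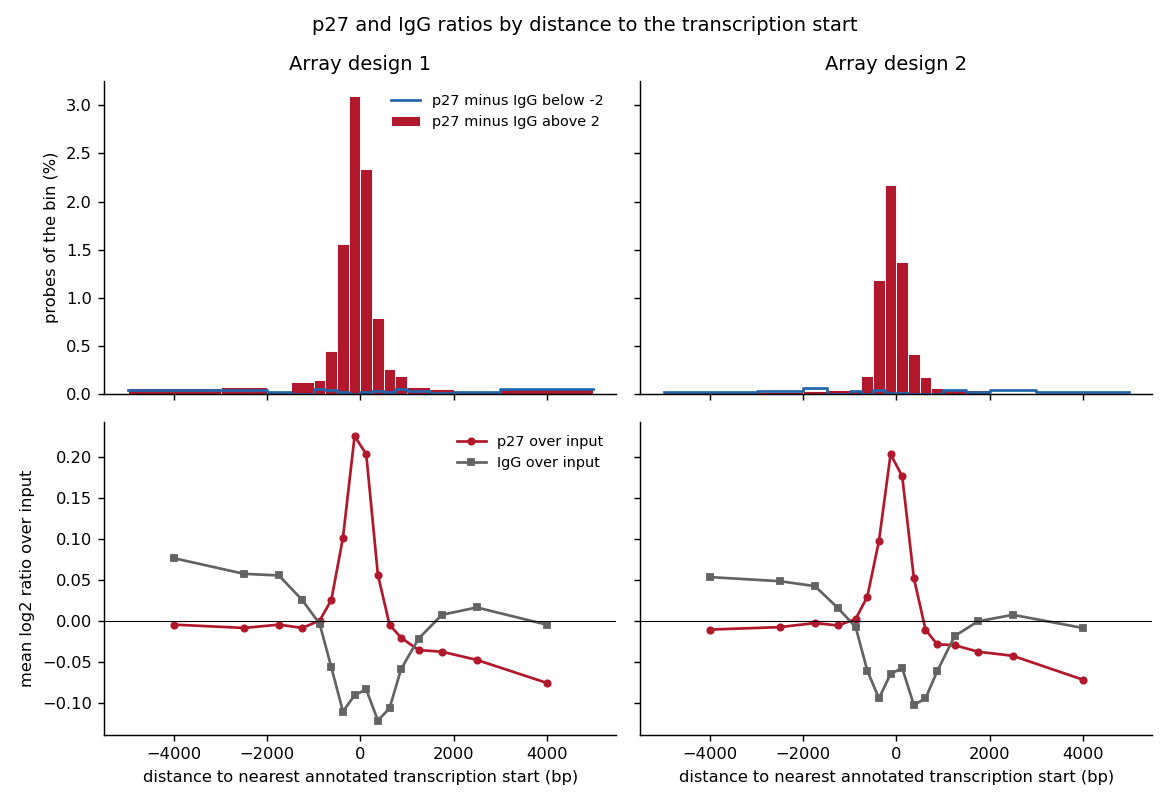
Percent of probes with a difference above 2 (red bars) or below -2 (blue line) in the upper panels, and mean log2 ratio over input of p27 (red) and IgG (grey) in the lower panels, by distance to the nearest annotated transcription start in bp, for each array design. From 250 bp upstream to the start, 3.10% and 2.17% of probes are above 2, and the mean p27 ratio is 0.23 and 0.20 where that of IgG is -0.09 and -0.06.

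The third comparison asked which kinds of genes carry p27 at their promoters. Genes of RNA splicing, protein synthesis and turnover, mitochondria and mitosis scored higher than genes of like probe number and signal, and olfactory receptors scored lowest. Each gene's score is its highest mean difference over 3 neighbouring probes, and each list's median score is set beside 10000 random lists matched on probe number and signal. Of 17 lists fixed in advance, 12 lay above the central 95% of the random lists, 3 below it and 2 within it. These percentiles describe these arrays and are not a test. Random lists were not matched on GC content or on divergent promoters, so promoter type and gene function cannot be told apart here. Splicing, mitochondria, translation and cell cycle were themes known from the study's publication when the lists were drawn up, so their lists are not independent evidence. Of the 993 genes in lists other than olfactory receptors, 51 were called (5.14%), against 2.35% of all genes, which include those receptors. Over all 17 lists, 51 of 1995 genes were called. Most members of each list were thus not called.

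Splicing genes led with a median score of 0.59, where random lists had a median of 0.02 and an upper limit of 0.13. Of 85 measured members 12 were called. They include Usp39 and Lsm3, parts of the spliceosome and its small nuclear particles, with differences of 3.40 and 3.32 over 3 probes each, and Dhx38, a helicase of the splicing reaction, with 3.11. The region of Usp39 is shared with Tmem150a and that of Dhx38 with Txnl4b, itself a splicing-related gene.

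The respiratory chain list had a median of 0.36, and 11 of 88 members were called, 9 of them with Ndufa, Ndufb, Ndufs or Ndufaf symbols of complex I or its assembly. Ndufs4 (3.38) and Ndufaf5 (3.08) were joined by Cox6c, a subunit of cytochrome c oxidase, with 3.30. Among 114 genes of the mitochondrial ribosome, import and maintenance, with a median of 0.38, 6 were called, among them Mrpl19 (4.48), Timm50 (3.16), a receptor of the inner membrane import machinery, and Mrpl22 (3.01).

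Cytosolic ribosomal proteins had a median of 0.41 and 5 of 85 members called: Rps12 (3.69), Rpl3 (3.66), Rpl34 (3.08), Rpl38 and Rps27a. Near-identical copies of ribosomal protein genes elsewhere in the genome make the assignment of these probes uncertain. Of 81 translation factors and tRNA synthetases, with a median of 0.31, 7 were called. They include Eif2b4 (3.34), a subunit of the exchange factor of initiation, Eef1b2 (3.20), an exchange factor of elongation, and Gspt1 (3.05), a termination factor. The region of Eif2b4 is shared with Snx17. That of Eef1b2 is shared with Ndufs1, so the same run also counts as a call in the respiratory chain list. Of 49 ubiquitin and proteasome genes, with a median of 0.43, 3 were called: Psmd9 (3.96), Psmc1 (2.59, at -2171 bp from its RefSeq start) and Psmd5 (2.06), which encode subunits or assembly chaperones of the proteasome.

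The mitosis list had a median of 0.34 with 3 of 43 members called. Nuf2, a kinetochore protein, had 3.05 over 2 probes, Kif11, a spindle motor, 2.33 over 3 probes and Aurka, a mitotic kinase, 2.23 over 2 probes; all 3 lost their call when the 2 arrays of a design were quantile-normalized, and on design 1 alone the list was at the 94.9th percentile. The replication list lay at the 98.6th percentile with 0 of 45 members called. Rfc4, a clamp loader subunit, had its highest score, 1.19, from a mean difference of 1.77 over 3 probes. The list of DNA repair lay at the 99.4th percentile with 2 of 43 called, Nbn (2.37) and Xpa (2.16). The p27 ratios in those regions were only 0.79 and 0.75, so both calls rest on a low IgG ratio. On design 2 alone the percentiles of replication and DNA repair were 60.2 and 92.2, and neither list was past the limit on either design alone. The list of kinase inhibitors, pocket proteins, E2F factors and D cyclins lay within the range of random lists at the 57.6th percentile, with 1 gene called above (Rbl2) and 1 called below (Cdkn1a) among its 29 members. By score, which takes the highest 3 probes, Cdkn1a was at the 89.7th percentile of all genes. With the mean over all probes as score the list was at the 99.6th percentile.

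Several lists were high without a single called gene. Histone genes of the replication-dependent clusters had a median of 0.10, where matched random lists had -0.18; on design 1, which holds 8 of the 60, they were at the 97.2th percentile. Their highest member, H1f3, had 1.57 over its highest 3 probes in a region shared with H4c6. The peak lies at -3180 bp from the RefSeq start of H1f3 and -207 bp from the nearest annotated start. Histone genes, like ribosomal protein genes, have near-identical copies, so the assignment of their probes is uncertain. Members that share a region are not separate observations. Fibroblast matrix and contractile genes had a median of 0.27, with Mmp14, a membrane-bound matrix protease, at 1.51. Serum-response genes had 0.29, with the transcription factor Jun at 1.89, but were at the 86.7th percentile on design 2 alone. The fibroblast list was also low by IgG over input, at the 0.28th percentile.

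Tissue-specific genes were at the other end. The 1002 olfactory and vomeronasal receptors had a median of -0.35 and no called member, and the highest of them, Olfr145, had 1.00. This list was at the 100th percentile by IgG over input and at the 0.0th by p27 over input. Each of these scores takes its own highest 3 probes, so they do not show which ratio sets the low difference. Immune cell genes lay at the 1.04th percentile (highest member Il5, a cytokine, 0.87) and developmental transcription factors at the 0.73rd. These positions became 10.7 for immune genes on design 2 alone, and 13.7 for developmental genes on design 1 alone. Matching on probe length as well moved developmental genes to 5.61. Neuronal synaptic genes were just within the range at the 3.06th percentile, but below it under 6 of 13 alternatives, between 0.0 (dim probes left out) and 2.47 (loess on signal). Their highest member, the receptor subunit Gabra2, had 1.12.

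**Figure D4:**
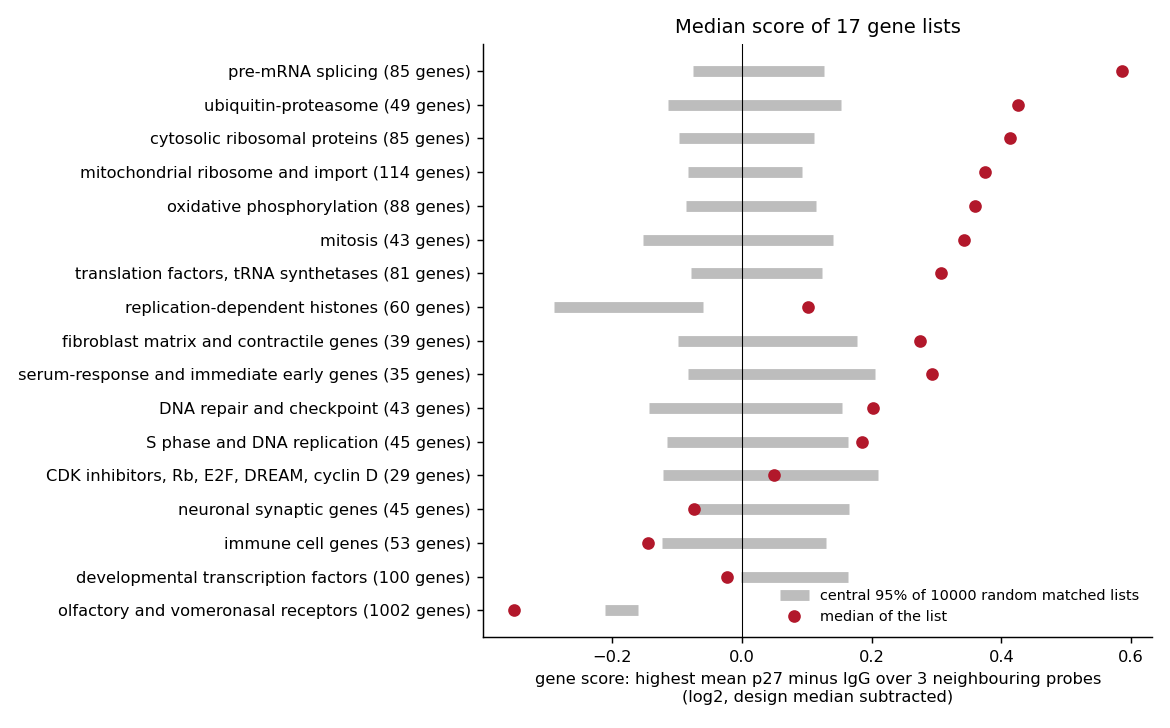
Median gene score (log2, horizontal axis) of 17 gene lists, red points, beside the central 95% of 10000 random lists matched on probe number and signal, grey bars, with the number of measured genes after each name. Splicing genes lie highest at 0.59 and olfactory receptors lowest at -0.35.

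The fourth comparison set these calls beside the authors' deposited gene and probe tables. The deposited gene table holds 447 gene labels, 186 with at least 2 consecutive probes and 261 with 1. Of the 447, 293 were also called here with at least 2 probes, 165 of them among the 186, and 389 had at least 1 probe above 2. The 2 genes with 5 consecutive probes in the deposited table and the first 3 of the 11 with 4, in file order, were called: Bbs5 (2.83 over 5 probes) and Med18, a Mediator subunit (3.0 over 4 probes), Aaas, a nuclear pore protein (3.45 over 3 probes), Copb1, a coat protein of Golgi vesicles (3.30 over 5 probes), and Sepsecs, which makes selenocysteyl-tRNA (3.48 over 4 probes). Called genes absent from the deposited table numbered 97. They include Wdr5, Uevld, Kctd3, Rtcb, Stxbp4, Psmd9 and Ndufaf5, with differences from 3.08 to 4.15.

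Most of the probes above 2 are not in the deposited probe table. It lists 578 of the 1779 and leaves out 1201 (67.5%). Every one of the 1201 had an IgG spot p-value of 0.05 or less, and none of the 578 had. With that limit on the IgG spot added, 152 genes were called. In the region of Psmd9, all 4 probes fall under it, and in that of Ndufaf5 all 5. Left-out probes had a lower median p27 ratio, 1.37 and 1.41 on designs 1 and 2, than listed probes, 2.67 and 2.64. Their median IgG ratio was also lower, -1.03 and -1.02 against -0.03 and -0.06. Both contrasts follow largely from the 2 limits. With a difference above 2, an IgG ratio near 0 requires a p27 ratio near 2 or more, and a low IgG ratio does not.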

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

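The tests of the single faulty spot, of the promoter pattern other than probe length and slide patches (isolated spots are among those chosen later), and of the IgG spot limit were chosen only after the result was seen.

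Signal in the control precipitate itself, which was otherwise only subtracted, stood above the highest negative control spots (0.75 and 0.66 on designs 1 and 2) at Cdkn1a and Zmat3, a pair that the tumour suppressor p53 is known to activate. Those spots vary little, with an SD of the difference of 0.10 and 0.13 against 0.56 and 0.49 for probes, so they set a low bar. The mean IgG ratio was 1.84 over 3 probes upstream of Cdkn1a (chromosome 17, 28818399 to 28818799), with the peak at -2667 bp from its start, and 1.79 over 3 probes inside Zmat3 (chromosome 3, 32555637 to 32555937), which encodes an RNA-binding zinc finger protein. The p27 ratios there were -0.07 and 0.59. These were the regions with the 2nd and 4th highest such IgG runs among 569 genes.

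At Cdkn1a, 3 neighbouring probes have an IgG ratio above 1, but the gene was picked by a run of neighbouring probes, so this does not decide about a single faulty spot. Chromatin precipitated with p53 in the IgG sample may explain both peaks, and the p53 list lay at the 98.85th percentile by IgG over input on design 2. Without Cdkn1a it was at the 93.72th, and on design 1 it was at the 61.04th, or the 65.56th without Zmat3, so this remains open. By IgG score 3 of the 36 targets, the pair and Eda2r (99.6th percentile), were in the top percent of all genes, while Mdm2, Bbc3 and Bax were at 66.6, 33.2 and 4.0. The low difference at Cdkn1a comes mainly from its IgG ratio of 2.22.

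The close fit of the p27 signal to transcription starts has technical explanations, and the tables argue against some forms of them. Base composition of the probes, with probe length as its stand-in, would flatten the pattern among the longest probes. Among those of 60 bases the share above 2 near starts was 25.8 times the share beyond 1000 bp in the lower design. Base composition can still vary among probes of 1 length and was not measured, nor was that of the longer precipitated fragments. That value thus argues only against a pattern carried by probe length. A fall of IgG alone would leave p27 over input flat, but its share above 2 was 134.3 times higher near starts. Amplification that favours promoters in any precipitate would raise IgG too. The mean IgG ratio near starts minus that beyond 1000 bp was -0.10 in the design with the higher value. A bias that differs between slides is not covered, and the cause of the lower IgG ratio near starts was not tested. Patches on the slides left a ratio of 1.35 over shuffled spots that does not decide, although 83.5% of the spots with no other such spot around them also lay near starts; a difference between single slides cannot be told apart from p27 at promoters, since there is 1 array per antibody and design.

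The probes left out of the deposited table are the third pattern. A limit on the IgG spot p-value accounts for it: 100% of the 1201 probes left out had a value of 0.05 or less. Noise in their IgG ratio stays open: they had a neighbouring probe above 2 at 50 times the shuffled share in the lower design, but a wide p27 peak gives such neighbours either way, and 43.3% and 38.4% of them had one, against 83.3% and 85.7% of listed probes. The probes next to them had median IgG ratios of -0.21 and -0.14 on designs 1 and 2, which met neither of the limits set in advance on both designs and does not decide. These medians were lower than those of all probes near starts, -0.07 and -0.05. Probes next to listed ones, and not above 2 themselves, had 0.07 and 0.05. The 2 sets of neighbours are selected differently, since those of left-out probes may include listed probes above 2. Requiring a difference of 2 or less also favours a higher IgG ratio, so the 2 sets cannot be compared. No biological explanation was tested.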

How the results depend on the processing

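The limit on the IgG spot, the joint limit on p27 over input, the matching on probe length or on probes near a start, and the position under p27 over input alone were chosen after seeing the data. Quantile normalization gave 438 probes and 92 genes on design 2. With p27 over input alone there were 550 and 378 probes above 2 on designs 1 and 2, with 96.5% and 95.5% near a start, and 292 of the 396 called genes were shared. Scanner processed signals gave 1804 probes above and 1646 below on design 1, and 451 genes above and 146 below in all, with 387 of the 396 shared. A threshold of 1.5 gave 3259 and 2038 probes, 553 and 333 genes, 506 and 301 runs, and 65.9% and 72.2% near a start. A threshold of 3 gave 286 and 164 probes, 83 and 45 genes, 78 and 40 runs, and 96.2% and 95.7%. Only probes with an IgG spot p-value above 0.05 gave 305 and 273 probes, 70 and 82 genes and an overlap of 166 with the deposited gene table, or 382 when 1 such probe sufficed. At least 1 probe gave 742 and 465 genes, and at least 3 probes gave 116 and 78 with an overlap of 174. Thresholds and run lengths change these counts by construction. For quantile normalization the cause was not tested. The scanner signals put 1 array of each pair on a wider scale than its partner, and how much of the change this accounts for was not tested.

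Centring, loess, normexp, dim probes left out, a threshold scaled by robust SD, the joint p27 limit and a gap of 500 bp kept both gene counts above within 1.5 times. Of the 64 named genes, 49 were called and 15 were not. Over 6 settings, 366 of 384 values kept this status, which includes the 15 genes, uncalled in every setting. The other 18 values were lost calls. Of the 49 called genes, 9 lost their call under quantile normalization, 8 under p27 over input alone, and Kcna6 under loess. Of 221 percentiles of lists over 13 settings, 195 kept their side of the limits, 19 no longer passed and 7 newly did, and none reversed. Centring cannot move a list percentile, and it gave 17 of the 195. Replication lost its place most often, with 87.35 under normexp and 83.71 with the highest single probe. Random lists matched on GC content were not run, since probe sequences were not used here. The median signal over background, 10.0 to 14.8 where scanner output was used, limits how small a ratio can be read.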

Other observations

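The gene families by symbol stem were chosen only after the result was seen.

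Gene families grouped by symbol stem show further groups with a shifted median score. Of 64 families with at least 20 members outside the fixed lists, 19 lay above the central 95% of matched random lists, 4 of these without a called gene, and 12 below it. Under all 6 other scalings tried, 9 of the 19 and 6 of the 12 stayed on their side, among them the 7 families named here. General transcription factors (Gtf) had a median score of 0.39 with 4 of 22 called: Gtf2b and Gtf2f2, which act with RNA polymerase II, and Gtf3c2 and Gtf3c3, which act with RNA polymerase III. DEAD-box helicases (Ddx), many of which act in splicing and translation, had 0.44 with Ddx41 and Ddx42 among the called. Mediator subunits (Med) had 0.29 with Med18, Med20 and Med6 called, and Vps genes had 0.35 with Vps33b and Vps50, which act in endosomal traffic, and Vps72, of histone variant exchange, called.

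At the low end were kallikreins (Klk, -0.61), cytochrome P450 genes (Cyp, -0.35) and keratins (Krt, -0.18), none with a called gene. The IgG ratio was lower near starts than far from them in each of 21 chromosome parts, by -0.157 to -0.081, and the p27 ratio was higher in each, by 0.071 to 0.243.

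Negative control spots, 1378 in all, had 0 differences above 2. Of 11568 probes assigned to no gene, 19 were above 2 (0.164%).

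The number of probes above 2 rose with signal on design 1, from 2 in the lowest of 10 equal classes of mean signal to 233 in the highest. On design 2 it rose from 1 to 145 in class 9, with 115 in the highest.

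The deposited probe table has 997 rows for 655 probes, with 342 repeated. Its differences exceed those recomputed from the tables of all spots by 0.11 on average (log2).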
